A study of Hypomesus transpacificus with 49 samples.

How the data were processed

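Gill RNA of delta smelt was measured on 49 arrays in 13 groups: handling controls and 3 warming ramps at 3 recovery times each, and tank controls. Per the labels, fish were acclimated for 3 weeks at 16 °C and given 30 min in the vessel before warming at 0.3 °C per min, and 200 ng of total RNA was labelled with Cy3 using a low-input amplification kit. The labels state 3 to 6 replicates per group, while the ramp to 22.4 °C at 60 min holds 2 arrays. The labels mention both larval and adult recovery tanks and do not give the life stage of any sample.

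Per the file headers, each scanner file holds intensity values extracted with Feature Extraction 11.5.1.1, background-subtracted and spatially detrended within the array, with no normalization between arrays. The same deposited files hold raw median intensity of spot and local background and marks for spots well above background, saturated or non-uniform. The deposited value table holds log2 values for 36878 probe names in 49 columns, of which 36818 matched sample probes, and 0 columns were left unused. Its column medians lie between -0.033 and 0.067, every column mean is 0.015, and 100% of its probes have a median over arrays within 0.01 of 0. Set against the scanner files on 20541 probes, its differences between arrays follow log2 intensity with slopes of 0.906 to 1.031 and r of 0.938 to 0.999. So its scale and direction were settled and each probe is centred over the arrays, while the method of normalization is not given in the sources used here. It was used as an alternative.

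Each array carries 38235 spots, with 1264 positive and 153 negative control spots. Of the spots for sample probes, 0.12% were marked as outliers and left out. Repeated spots were averaged for spike-in probes only. The log2 intensity minus the array's 75th percentile was analysed for the 33910 probes well above background on at least 3 arrays; 21585 were so on every array. The spike-in level of an array is the median log2 intensity of 10 spike-in probes minus that percentile. Handling control replicates 3 and 5 at 30 min share slide and position, and their log2 values differ with an SD of 0.315 (r = 0.9932), against at least 0.633 in 73 other pairs within groups. They were averaged as scans of 1 hybridisation after this was seen, which leaves 48 arrays in the fit where the plan had 49, and keeping both was run as an alternative. Arrays lie on 14 slides scanned on 3 days. Deviations from group means correlated at 0.168 on average within a slide, at 0.034 between slides of the same day and at -0.031 between days, and the consensus correlation within slides was 0.232.

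A one-way moderated fit in the manner of limma (limma 3.58.1, with its moderated variances, in R 4.3.3; files were read with version 1.17.8 of data.table) pooled the spread over the 13 groups and gave 19 comparisons, two-sided, with Benjamini-Hochberg adjustment within each and a threshold of 0.05. The lone array left in a group when its mate was dropped is assumed to vary like the other groups. Probe sets were compared by exact two-sided permutation of arrays. Probes next to each other in the design had a median correlation of deviations of 0.61, against 0.02 for random pairs, so probes with consecutive numbers and a correlation over 0.5 were counted as a run. Figures used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

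The fit was tested on simulated data with 200 of 33910 probes changed. For 26.4 °C against handling controls at 30 min it recovered 25.4%, 70.1% and 98.5% of changes of 1, 2 and 4 log2 units with 7 false calls. For 26.4 °C it recovered 16.4%, 65.7% and 90.9% at 0 min, and 40.3%, 82.1% and 98.5% at 60 min. For 24.4 °C at 30 min it recovered 19.4%, 77.6% and 93.9%, and for 22.4 °C at 60 min 16.4%, 73.1% and 93.9%. It made 0 calls in each of these comparisons when nothing was changed. The simulated noise was independent between probes and arrays, with no slide, scan day or link between neighbouring probes. So these values do not show how many false calls the real arrays give.

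Groups, comparisons, tests, 24 lists of genes, cell-type markers, the rule for named genes and most alternatives were fixed before the data were examined. That rule took the 8 largest rises and 8 largest falls per 26.4 °C comparison and 4 of each elsewhere, among probes paired with a gene name whose arrays do not overlap between groups. It could not be applied, nor could the lists or markers be tested, since the annotation used here gives no link from probe identifiers to genes. The alternatives were quantile normalization, the value table, no filter or a stricter filter on dim probes, the compared groups alone, slide as a random or fixed block, scan day or replicate number as a block, no arrays marked as redone, at least a 2-fold change, pooled handling controls, and leaving out each array. Chosen after seeing the data were normexp on median intensity with an offset of 50, both scans kept, the spike-in level as a covariate, leaving out 4 arrays with a high spike-in level, and array quality weights.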

Results

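Gill RNA of the delta smelt (Hypomesus transpacificus), a small estuarine fish, was measured on 49 single-colour Agilent arrays that carry 36818 probes for sample RNA. Fish kept at 16 °C were warmed by 0.3 °C per min to 22.4, 24.4 or 26.4 °C. These peaks lie 6, 4 and 2 °C below CTmax, the critical thermal maximum of an acute warming test. Gills were taken at the peak (0 min) or after 30 or 60 min of recovery at 16 °C. Handling controls went through the vessels and transfers with no warming and gave 3, 5 and 6 arrays at 0, 30 and 60 min. The ramp to 22.4 °C gave 4, 4 and 2 arrays at these times, the ramp to 24.4 °C gave 3, 3 and 4, and the ramp to 26.4 °C gave 4 at each. A further 3 arrays came from tank controls, whose treatment the labels do not describe further. The p-values measure only the spread between samples, since the labels do not say that each sample is a separate fish. The number of arrays limits the precision of every value.

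On the log2 scale the 75th percentile of sample signal ran from 5.59 to 8.77 over the arrays, with a median of 7.6. Between 68.8% and 91.5% of sample probes were well above background on an array, with a median of 83.5%. No gene names could be tied to the probes, so changes are given by probe identifier and by run. A run is a stretch of consecutive design numbers whose probes vary together between arrays of a group. The 33910 tested probes formed 16371 runs, so 1 transcript can be counted through several probes. The 3 probes named were chosen after their values were seen: the strongest rising run, a second rising run, and the strongest falling run.

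The ramp to 26.4 °C asks what gill RNA does close to the thermal limit. CUST_8949_PI428861894, a member of a run of 4 adjacent probes, rose at each recovery time against handling controls of that time. Its log2 change was 4.47 (SE 0.60; n = 4 and 3; 22.2-fold) at 0 min, 6.30 (SE 0.56; n = 4 and 4; 78.6-fold) at 30 min and 5.14 (SE 0.51; n = 4 and 6; 35.2-fold) at 60 min. CUST_34573_PI428861894, in a run of 2, fell by 3.31 (SE 0.27; 9.92-fold), 2.71 (SE 0.25; 6.55-fold) and 2.66 (SE 0.23; 6.34-fold) at the same times. CUST_24606_PI428861894, in another run of 2, rose 7.84-fold at 30 min (log2 2.97, SE 0.40) and 4.33-fold at 60 min (log2 2.12, SE 0.36), while its change at 0 min was 1.55 (SE 0.43). This probe was well above background on 3 of 5 handling control arrays at 30 min and 5 of 6 at 60 min. So the size of its rise rests partly on control values near background. In limma with Benjamini-Hochberg adjustment, the adjusted p at 0, 30 and 60 min was 4.82e-05, 1.28e-09 and 2.88e-08 for CUST_8949_PI428861894. It was 2.05e-10, 1.65e-09 and 9.14e-10 for CUST_34573_PI428861894, and 0.614, 2.03e-05 and 0.00249 for CUST_24606_PI428861894. Over the alternatives the log2 change of CUST_8949_PI428861894 ran from 3.64 to 5.05, 5.09 to 6.51 and 4.62 to 5.73 at 0, 30 and 60 min, lowest at 30 min with slide as a fixed block. That of CUST_34573_PI428861894 ran from -3.47 to -2.67, -2.93 to -2.25 and -3.05 to -2.13. For CUST_8949_PI428861894 the call at 0 min ended when the compared groups were fitted alone (adjusted p = 0.381; range over alternatives 1.9e-07 to 0.381). For CUST_24606_PI428861894 the call at 30 min ended with normexp background correction (log2 1.14, adjusted p = 0.136) and with slide as a fixed block (2.02, 0.384), against a range of 3.14e-07 to 0.384. Its call at 60 min ended with normexp (0.43, adjusted p = 0.737) and with the compared groups alone (2.12, 0.268), against a range of 2.57e-05 to 0.737.

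**Figure D1:**
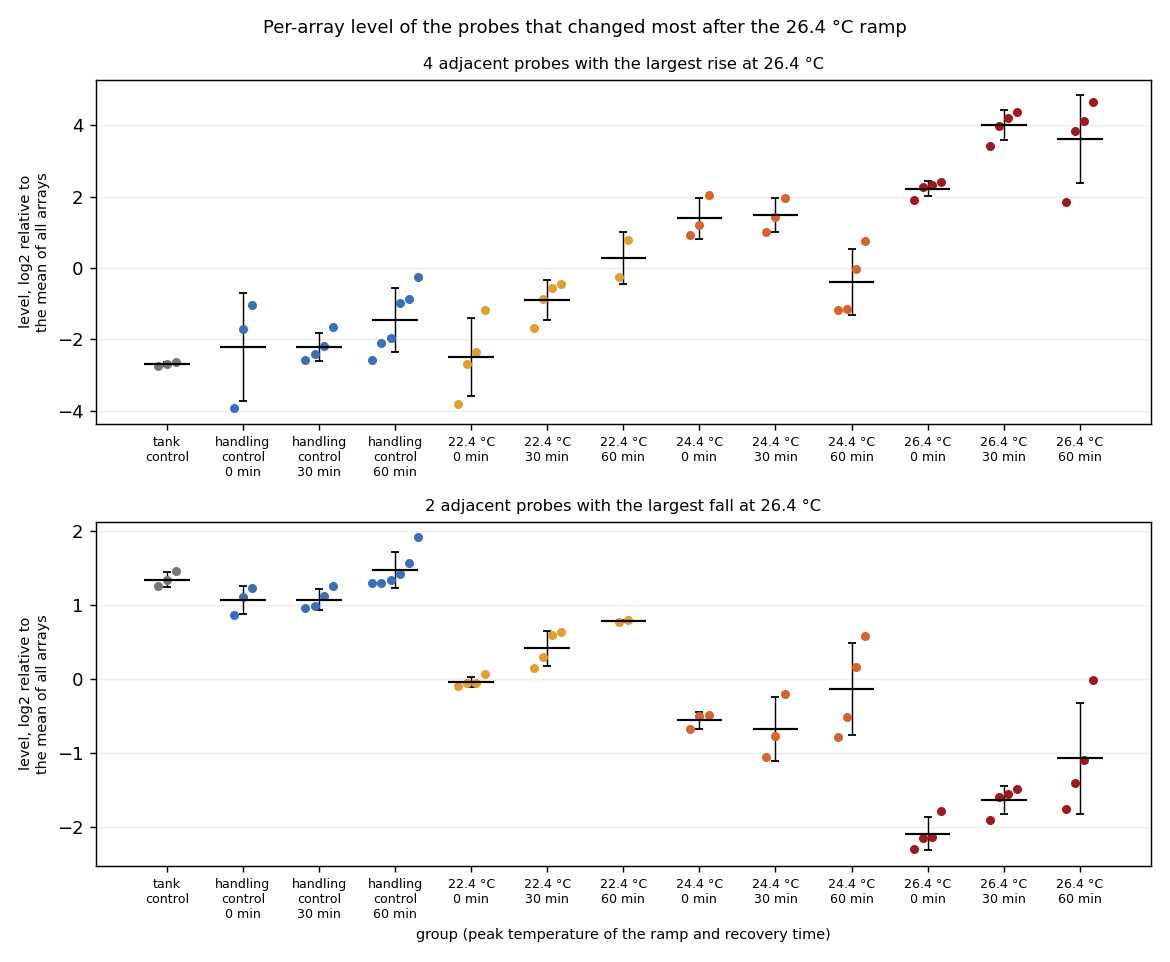
Mean level per array (points) of the 4 adjacent probes that rose most and the 2 adjacent probes that fell most at 26.4 °C, in log2 units relative to the mean of all arrays, with group means and SD bars. At 26.4 °C and 30 min the rising run sits between 3.43 and 4.39, against -2.57 to -1.66 in handling controls of that time.

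As a whole, the run of 4 rising probes stood 21.8-, 74.2- and 33.5-fold above handling controls at 0, 30 and 60 min after 26.4 °C, with all 4 heated arrays above all controls at each time. The exact two-sided permutation p was 0.0286, 0.0286 and 0.00476, and 0.0826 in each case after Benjamini-Hochberg adjustment over 26 tests of the run. The run of 2 falling probes differed by -3.16, -2.71 and -2.54 (log2), with exact two-sided permutation p of 0.0286, 0.0286 and 0.00476 and an adjusted value of 0.0572 over 26 tests. These runs were picked on the same arrays. Within single scan days, the rising run differed by 2.95 to 5.22 at 0 min, 5.75 to 6.6 at 30 min and 4.54 to 5.9 at 60 min. The falling run differed within days by -3.46 to -2.63, -3.15 to -2.5 and -2.7 to -2.29.

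Few other probes passed the main test after 26.4 °C. At 0 min 8 probes rose (3 runs) and 10 fell (7 runs), at 30 min 24 rose (15 runs) and 5 fell (4 runs), and at 60 min 44 rose (23 runs) and 24 fell (17 runs), all in limma at a Benjamini-Hochberg adjusted p under 0.05. At all 3 times 6 probes were higher (2 runs) and 2 were lower (1 run). Calls at 30 and 60 min shared 16 rising probes (7 runs), where independent lists would share 0.031, and 3 falling probes (2 runs), where they would share 0.0035. The lists are not independent, since neighbouring probes are counted separately and both use the spread pooled over the 13 groups. The excess over these values is therefore overstated. The balance of higher and lower calls moved with the processing. At 0 min quantile normalization gave 8 higher and 6 lower, and normexp, which also starts from the median signal with no spatial detrending, gave 7 and 2. At 60 min quantile normalization gave 59 and 14, the deposited values gave 57 and 16, and normexp 47 and 2.

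The counts at 26.4 °C also moved when single arrays were left out, with slide as a block and within a scan day. Blocks and single days leave less data to estimate the spread, so a lower count there need not come from batch. Of 29 calls at 30 min, 17 were left without handling control replicate 2 and 16 without replicate 4. The 68 calls at 60 min became 38 and 40 without handling control replicates 3 and 4, and 611, 19, 185 and 20 without heated replicates 1, 3, 4 and 5. With slide as a fixed block 6 probes were called at 30 min and 410 at 60 min. On scan day 1 alone (2 heated and 4 control arrays) limma called 0 at 60 min, and every other day held too few arrays of both groups for a count at any time. With the compared groups fitted alone the counts were 2, 12 and 8 at 0, 30 and 60 min. Pooled handling controls gave more calls than the main fit at each time, and array weights gave more at 0 and 30 min. Without arrays of high spike-in level there were more at 30 and fewer at 60 min. These counts are given with the processing below.

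Whether the response to 26.4 °C itself changed between 0 and 60 min was tested as a difference of differences. In limma no probe passed (0 calls; smallest Benjamini-Hochberg adjusted p = 0.968), and 1544 probes, 4.55% of those tested, had an unadjusted p under 0.05. Without the 60 min heated replicate 1 the count was 2. The second falling run of 2 probes was -2.34 against controls at 0 min and -0.47 at 30 min (log2). At 0 min, 1 of its 2 probes was well above background on 0 of the 4 heated arrays and on all 3 controls. So the size of this fall rests on values near background. The run's level at 26.4 °C was 1.80 higher at 30 than at 0 min (exact two-sided permutation p = 0.0286, adjusted 0.0676 over 26 tests). The run was picked for its fall on the same arrays at 0 min. The choice itself favours a later rise, and the permutation test does not allow for it. Over 4 runs, 3 ramps and 3 pairs of times, none of 36 exact two-sided permutation tests of a changed response passed the Benjamini-Hochberg adjustment (lowest adjusted p = 0.864). These tests exchange heated and control arrays within each time, so a large response at either time widens the values they compare with. They could hardly pass for a large response and do not show that it stayed the same. At 26.4 °C the level of the rising run of 4 was 1.77 higher at 30 min, where it was picked, than at 0 min (exact two-sided permutation p = 0.0286, adjusted 0.0826 over 26 tests).

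After 24.4 °C, CUST_8949_PI428861894 and CUST_34573_PI428861894 were called in the directions seen at 26.4 °C, except CUST_8949_PI428861894 at 60 min. CUST_8949_PI428861894 rose 12.7-fold at 0 min (log2 3.67, SE 0.64; n = 3 and 3) and 13.1-fold at 30 min (3.71, SE 0.60; n = 3 and 4), and its change at 60 min was 1.11 (SE 0.51; n = 4 and 6; 0.43 to 1.83 over the alternatives). CUST_34573_PI428861894 fell by 1.81 (SE 0.29), 1.80 (SE 0.27) and 1.65 (SE 0.23) at 0, 30 and 60 min, which is 3.51-, 3.47- and 3.14-fold. In limma the Benjamini-Hochberg adjusted p at 0, 30 and 60 min was 0.0116, 0.00269 and 0.39 for CUST_8949_PI428861894. It was 0.00644, 0.00189 and 0.000311 for CUST_34573_PI428861894. CUST_24606_PI428861894 was not called at 24.4 °C, with changes of 1.63 (SE 0.46), 1.65 (SE 0.43) and 0.40 (SE 0.36) and limma Benjamini-Hochberg adjusted p of 1, 0.594 and 0.702. Of its alternatives only array weights at 30 min gave a call (1.64, adjusted p = 0.00423; range 0.00423 to 1). With 3 arrays against 3 at 0 min, an exact permutation test of the rising run could not go below the 0.1 it gave. Within scan days that run differed by 3.08 to 3.88 at 0 min and 3.70 to 3.94 at 30 min.

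Over the alternatives the log2 change of CUST_8949_PI428861894 at 24.4 °C was 2.84 or more at 0 min, with an adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment in 17 of 22. At 30 min it was 2.92 or more, and 21 of 23 passed. That of CUST_34573_PI428861894 ran from -1.97 to -1.68 (18 of 22 passed), -2.02 to -1.54 (21 of 23) and -1.89 to -1.42 (25 of 26) at 0, 30 and 60 min. For CUST_8949_PI428861894 at 0 min the adjusted p was 1 with the compared groups alone, 0.44 without handling control replicate 2, and 0.0637 and 0.193 without heated replicates 4 and 5 (range over alternatives 7e-04 to 1). At 30 min it was 0.778 with slide as a fixed block and 0.0924 without heated replicate 1 (range 1.01e-06 to 0.778). For CUST_34573_PI428861894 at 0 min it was 0.431 with the groups alone, and 0.0624 and 0.07 without heated replicates 4 and 5 (range 5.31e-06 to 0.431). At 30 min it was 0.348 with the groups alone and 0.446 with slide fixed (range 2.95e-06 to 0.446), and at 60 min 0.129 with the groups alone (range 3.68e-05 to 0.129).

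At 24.4 °C limma with Benjamini-Hochberg adjustment called 5 probes higher and 3 lower at 0 min, 8 and 2 at 30 min, and 2 and 43 at 60 min. At 60 min the spike-in level was -0.13 ± 0.75 (SD, n = 4), with replicate 3 at 0.73, against -0.89 ± 0.42 (SD, n = 6) in controls. The 45 calls there became 10 with the spike-in level as a covariate, 16 with array weights (0.15 for replicate 3) and 57 without arrays of high spike-in level. Quantile normalization gave 6 and 2, 6 and 3, and 9 and 40 at these times. The value table gave 6 and 2 at 0 min, 7 and 3 at 30 min and 9 and 43 at 60 min, and normexp 4 and 1 at 0 min and 2 and 2 at 60 min. Of the 8 calls at 0 min, 5 and 3 were left without handling control replicates 1 and 2, and 0 without heated replicate 4 or 5. Of the 10 at 30 min, 6 were left without handling control replicate 2 or 4, and 1 without heated replicate 1. The 45 at 60 min became 20, 29, 29, 18 and 17 without handling control replicates 3, 4, 5, 6 and 7, and 78, 124 and 167 without heated replicates 1, 2 and 6. With slide as a fixed block the counts were 5, 0 and 2. Within scan days, day 3 gave 0 at 0 min, and days 1 and 3 gave 4 and 0 at 60 min, while no day held enough arrays at 30 min. Array weights at 30 min and pooled handling controls at 0 and 60 min called more probes than the main fit, with counts given below.

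At 22.4 °C only 2 probes of 1 run passed at 0 min and the same 2 at 30 min, all higher. Their largest log2 change was 2.45 at 0 min and 2.11 at 30 min, with smallest limma Benjamini-Hochberg adjusted p of 3.39e-05 and 0.000189 (n = 4 and 3, and 4 and 4). Of the alternatives that tested these 2 probes, CUST_14542_PI428861894 and CUST_14543_PI428861894, each passed in 20 of 22 at 0 min and 20 of 23 at 30 min. The limit to probes above background on every array removed both, so it did not test them. With normexp their changes were 0.95 and 0.87 at 0 min (adjusted p = 0.997 for both) and 1.19 and 1.11 at 30 min (0.0714 and 0.266). With the compared groups alone the adjusted p was 0.238 at 0 min and 0.32 at 30 min on the same changes, and with slide as a fixed block at 30 min they were 1.93 and 1.98 (0.274 and 0.248). The adjusted p over alternatives ran up to 0.997 at 0 min and 0.32 at 30 min, from 1.86e-05 and 2.59e-05 at 0 min and 6.66e-08 for both at 30 min. Each of these fits called 0, and within scan day 3 limma called 0 at either time. At an unadjusted p under 0.05, 1856 probes passed at 0 min and 1253 at 30 min. The log2 change of CUST_8949_PI428861894 was -0.27 (SE 0.60) at 0 min and 1.31 (SE 0.56) at 30 min, and that of CUST_34573_PI428861894 was -1.29 (SE 0.27) and -0.61 (SE 0.25). None of these 4 changes passed (limma Benjamini-Hochberg adjusted p = 0.985, 1, 0.181 and 1). As a whole, the falling run of 2 differed by -1.10 (SE 0.12) at 0 min and -0.66 (SE 0.14) at 30 min, with all 4 heated arrays below all controls. The exact two-sided permutation p was 0.0286 at both times, adjusted 0.0572 over 26 tests. At 0 min the run was picked against the same controls, which favours a fall. The rising run of 4 differed by -0.28 and 1.32 (exact two-sided permutation p = 0.771 and 0.0571). At 22.4 °C, pooled handling controls at 0 min and array weights at 30 min called more probes than the main fit, with counts given below.

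The 2 arrays of 22.4 °C at 60 min gave the largest count of the 19 comparisons. In limma with Benjamini-Hochberg adjustment, 954 probes were higher (578 runs) and 1835 lower (1127 runs) than in the 6 handling controls, with log2 changes from -5.35 to 7.44 and a smallest adjusted p of 0.000252. On these 2 arrays the spike-in control RNA stood at 0.10 ± 0.22 (SD, n = 2) relative to the 75th percentile of sample signal, against -0.89 ± 0.42 (SD, n = 6) in the controls. The count was 14 with the spike-in level as a covariate, 669 without heated replicate 2 and 244 without replicate 4. It was 7983 with slide as a fixed block and 5845 with slide as a random block, and no scan day held enough arrays. Normexp turned the balance to 274 higher and 104 lower.

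**Figure D2:**
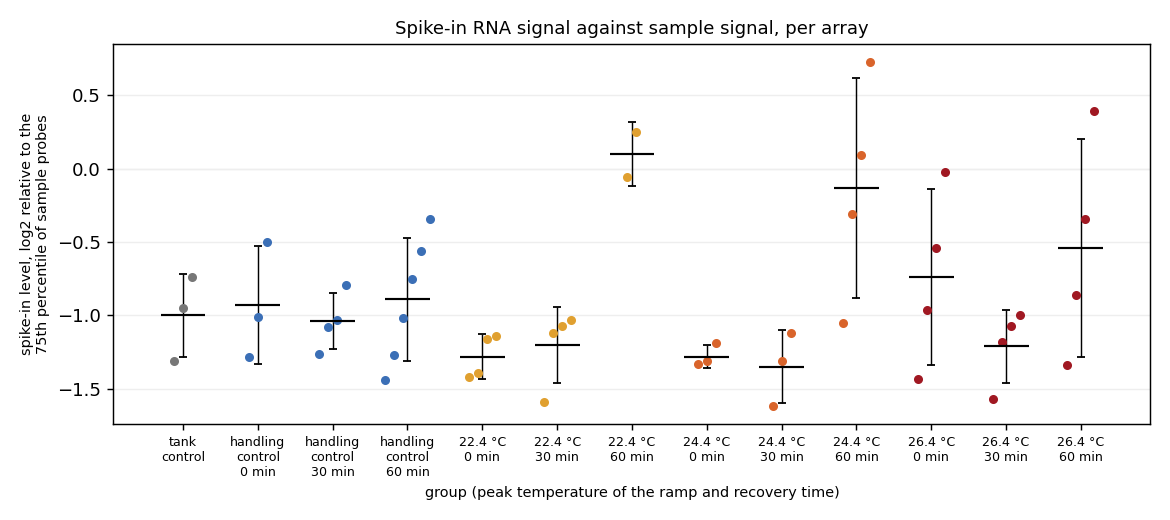
Spike-in RNA level of each array (points), in log2 units relative to the array's 75th percentile of sample signal, with group means and SD bars. The arrays at 60 min after warming reach up to 0.73, while those at 30 min after warming stay at or below -1.0.

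Across ramps, the 54 probes that rose at 26.4 °C at any time had median log2 changes of 0.03, 0.35 and 0.53 at 22.4 °C, 0.72, 0.53 and 0.28 at 24.4 °C, and 0.50, 1.01 and 1.39 at 26.4 °C, for 0, 30 and 60 min. The 31 probes that fell had medians of -0.14, -0.33 and -0.64, then -0.42, -0.31 and -0.49, then -0.66, -0.71 and -1.17. The values at 26.4 °C are those the probes were picked on, and at each time the other ramps share the controls that picked them. Against handling controls of the other times, the probes that rose at 0, 30 and 60 min had medians at that time of 2.30, 0.70 and 0.43 at 24.4 °C, beside 2.81, 1.08 and 0.25 against controls of the same time. At 22.4 °C these were -0.27, 0.25 and 0.64, beside 0.26, 0.60 and 0.76. The probes that fell had -0.89, -0.21 and -0.41 at 24.4 °C, beside -0.62, -0.69 and -0.52, and -0.89, -0.31 and -0.58 at 22.4 °C, beside -0.82, -0.68 and -0.71. At 30 min, changes at 24.4 and 26.4 °C correlated at r = 0.63 over 32794 probes, which are not independent replicates. Unchanged groups sharing these controls gave 0.46 in 100 simulated draws, and split controls gave 0.20. The covariance was 0.165, beside 0.104 with no effect. The draws took noise as independent between probes and arrays, so they do not show how far r varies between real unchanged groups. The excess over them at 30 min is therefore not shown to be a shared response. At 0 min r was 0.55 against 0.53 with no effect and the covariance 0.126 against 0.139, with too few controls to split, so shared controls alone can give this correlation. At 60 min r was 0.33 against 0.40, and 0.07 with split controls, and the covariance was 0.081 against 0.07. Between 22.4 and 26.4 °C at 60 min r was 0.63, against 0.32 with no effect and 0.43 with split controls, on the 2 arrays of 22.4 °C with the high spike-in level. Their calls shared 13 rising and 8 falling probes, but both ramps were set against the same 6 controls, and no value for unchanged groups sharing them was computed.

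**Figure D3:**
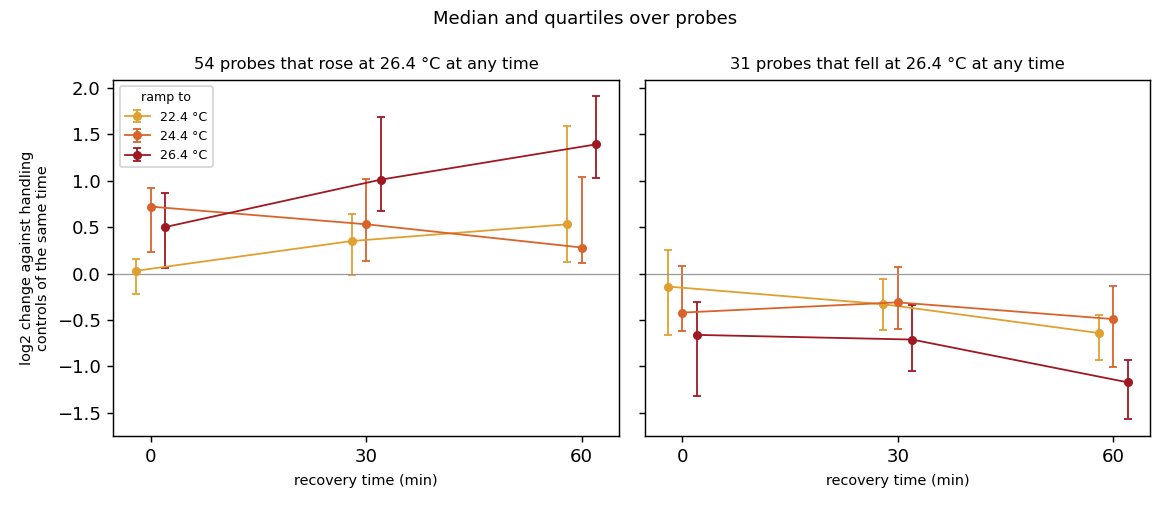
Median and quartiles over probes of the log2 change against handling controls of the same time, by recovery time in min and ramp, for the 54 probes that rose and the 31 that fell at 26.4 °C. The rising probes reach a median of 1.39 at 26.4 °C and 60 min, and 0.28 at 24.4 °C.

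Direct tests between ramps show where the responses differed. At 60 min CUST_8949_PI428861894 was 16.3-fold higher after 26.4 than after 24.4 °C (log2 4.02, SE 0.56; n = 4 and 4), and CUST_24606_PI428861894 was 3.29-fold higher (1.72, SE 0.40). The run of 2 that holds CUST_24606_PI428861894 differed there by 1.70 (exact two-sided permutation p = 0.0857, adjusted 0.248 over 26 tests), and by 0.16 with normexp. CUST_34573_PI428861894 was lower after 26.4 °C by a log2 difference of -1.50 (SE 0.27) at 0 min and -1.01 (SE 0.25) at 60 min. Its run of 2 differed by -1.53 at 0 min (exact two-sided permutation p = 0.0286, adjusted 0.0572 over 26 tests) and -0.93 at 60 min (p = 0.114, adjusted 0.148), where 3 of 4 arrays lay below all of the 24.4 °C arrays. The limma Benjamini-Hochberg adjusted p of these probe differences was 8.38e-05, 0.036, 0.0281 and 0.048 in that order. Over the alternatives the first ran from 3.12 without arrays of high spike-in level (adjusted p = 0.0659) to 4.70 with slide as a fixed block, and 21 of 23 passed, with an adjusted p of 9.17e-07 to 0.714, the last with the compared groups alone. The other 3 passed in 11 of 22, 12 of 22 and 8 of 23, with log2 differences of 0.14 to 2.19, -1.64 to -0.99 and -1.40 to -0.66. That of CUST_24606_PI428861894 was not called without 24.4 °C replicates 2 and 6 (1.73 and 1.46) or 26.4 °C replicates 3, 4 and 5 (1.69, 1.43 and 1.57). That of CUST_34573_PI428861894 was not called at 0 min without 24.4 °C replicates 2, 4 and 5 (-1.48, -1.52 and -1.49) or 26.4 °C replicates 2, 3 and 4 (-1.50, -1.37 and -1.48). At 60 min it was not called without 24.4 °C replicates 1 and 3 (-0.88 and -0.91) or 26.4 °C replicates 3, 4 and 5 (-0.97, -0.81 and -0.87). At 0 and 30 min the 26.4 to 24.4 °C difference of CUST_8949_PI428861894 was 0.80 and 2.59 (limma Benjamini-Hochberg adjusted p = 1 and 0.285). Over the alternatives it ran from -0.31 with slide as a fixed block to 1.18 at 0 min, where 0 of 22 passed. At 30 min it ran from 2.17 to 2.83, and 1 of 22 passed (limma Benjamini-Hochberg adjusted p = 0.012). Its run of 4 differed by 0.84 (SE 0.35), 2.52 (SE 0.35) and 4.01 (SE 0.77) at 0, 30 and 60 min. The exact two-sided permutation p was 0.0571, 0.0286 and 0.0286, and 0.099, 0.0826 and 0.0826 adjusted over 26 tests. So a difference at 30 min is not excluded, while the run was picked for its rise at 26.4 °C and 30 min, which favours that gap. For the run of 4 probes the gap at 60 min exceeded that at 0 min by 3.17 (exact two-sided permutation p = 0.0686 over 2450 regroupings), and that at 30 min by 1.48 (p = 0.465). For the falling run of 2 the gap changed by 0.60 from 0 to 60 min (exact two-sided permutation p = 0.492) and by 0.03 from 30 to 60 min (p = 0.966). These tests of both runs exchange the 2 ramps within each time, so a real gap at either time widens the values they compare with. Their p-values therefore cannot decide whether a gap changed with time. Between 24.4 and 22.4 °C, CUST_8949_PI428861894 was 15.3-fold higher at 0 min (log2 3.94, SE 0.60; limma Benjamini-Hochberg adjusted p = 0.00074; 3.43 to 4.78 over the alternatives, of which 21 of 22 passed). At 30 and 60 min this difference was 2.40 and -0.67 (adjusted p = 0.756 and 0.651).

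Limma with Benjamini-Hochberg adjustment called 2 probes higher and 1 lower at 26.4 than at 24.4 °C at 0 min, 2 and 0 at 30 min, and 104 and 56 at 60 min. The 3 calls at 0 min became 0 without 24.4 °C replicate 2 or 4 or 26.4 °C replicate 2 or 4, and 1 without 26.4 °C replicate 1. The 2 calls at 30 min became 0 (974 probes at an unadjusted p under 0.05 with all arrays) without any 1 of the 7 arrays. At 60 min the 160 calls became 543 and 69 without 24.4 °C replicates 1 and 3, and 247, 57 and 22 without 26.4 °C replicates 1, 4 and 5. Slide as a fixed block gave 0, 0 and 18 at the 3 times, scan day as a fixed block gave 0 at 0 min, and scan day 1 alone gave 31 at 60 min. Normexp gave 0, 0 and 52, the last with 46 higher and 6 lower.

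A set of 6 probes in 3 runs was lower at 24.4 than at 22.4 °C at both 0 and 30 min. Its mean level over all times, in log2 relative to the mean of all arrays, was 1.0 ± 0.37 (SD, n = 10) at 22.4 °C, -1.22 ± 0.40 (SD, n = 10) at 24.4 °C and 0.49 ± 0.40 (SD, n = 12) at 26.4 °C. Handling controls were at 0.02 ± 0.41 (SD, n = 13) and tank controls at -1.33 ± 0.06 (SD, n = 3). At 60 min, on arrays not used to pick the set, 26.4 exceeded 24.4 °C by 1.78 (SE 0.15; n = 4 and 4; exact two-sided permutation p = 0.0286, adjusted 0.0496 over 26 tests). At 60 min 24.4 and 22.4 °C differed by -2.01 (SE 0.48; n = 4 and 2; exact two-sided permutation p = 0.0667, the smallest these arrays allow). On the 5 slides that held both ramps, each with arrays that picked the set, 22.4 °C lay above 24.4 °C by 1.83 to 2.56.

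Limma with Benjamini-Hochberg adjustment called 4 probes higher and 7 lower at 24.4 than at 22.4 °C at 0 min, 2 and 8 at 30 min, and 74 and 29 at 60 min. The 11 calls at 0 min became 7 without 24.4 °C replicate 2. The 10 at 30 min became 3, 3, 6 and 5 without 22.4 °C replicates 1, 2, 3 and 4, and 2, 3 and 4 without 24.4 °C replicates 1, 2 and 3. The 103 at 60 min became 46 and 31 without 22.4 °C replicates 2 and 4, and 1631, 42, 765 and 59 without 24.4 °C replicates 1, 2, 3 and 6. Slide as a fixed block gave 5 at 30 min and 2542 at 60 min, scan day as a fixed block gave 192 at 60 min, and scan day 3 alone gave 2 at 0 min. Normexp gave 4 higher and 4 lower at 0 min, and 0 and 2 at 60 min.

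**Figure D4:**
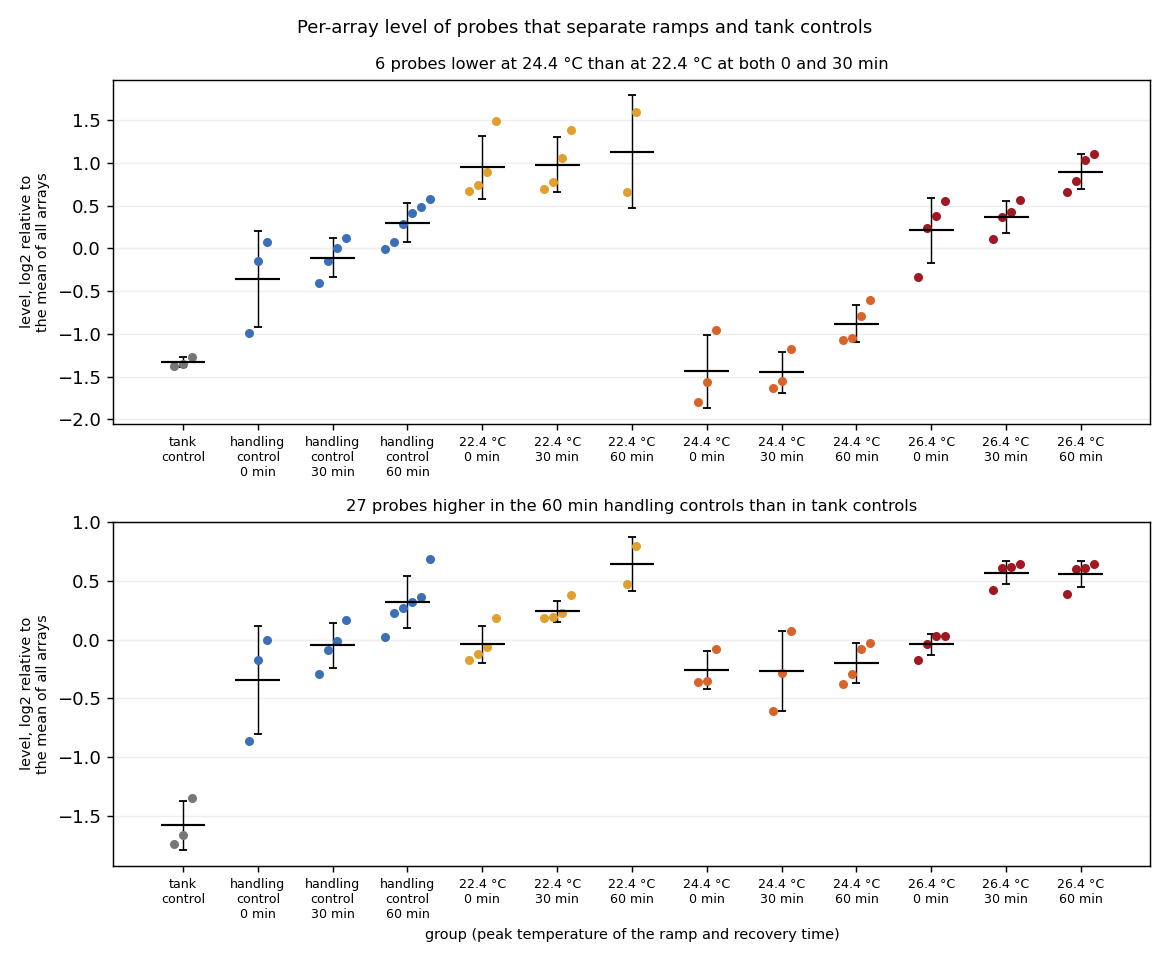
Mean level per array (points) of the 6 probes lower at 24.4 than at 22.4 °C and of the 27 probes higher in 60 min handling controls than in tank controls, in log2 units relative to the mean of all arrays, with group means and SD bars. The 6 probes sit between -1.80 and -0.60 at 24.4 °C and between 0.66 and 1.60 at 22.4 °C.

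Handling alone was compared with tank controls. At 60 min 27 probes (16 runs) were higher and 1 was lower in handling controls, with log2 changes from -1.05 to 2.96 (n = 6 and 3; smallest limma Benjamini-Hochberg adjusted p = 0.00324). The 27 probes averaged 3.73-fold higher (log2 1.90, SE 0.15), and the set mean of every other moved group lay above the tank controls as well, by 1.24 to 2.22. These probes were picked against the same 3 tank controls. That choice by itself favours a higher level in every other group, so these differences are no independent support. Of the 27, 5 are also among the 6 probes lower at 24.4 than at 22.4 °C, and these differed from tank controls by -0.13 (SE 0.24), -0.10 (SE 0.15) and 0.38 (SE 0.18) at 24.4 °C at 0, 30 and 60 min. The mean of the other 22 lay 1.27 or more above tank controls in each moved group. At 0 and 30 min limma called 0 probes (smallest adjusted p = 0.517 and 0.0845), with 1495 and 936 at an unadjusted p under 0.05. The set mean was 1.24 (SE 0.29) above tank controls at 0 min and 1.53 (SE 0.15) at 30 min. The difference between times was not tested for these counts. The 28 calls at 60 min became 15 and 13 without handling control replicates 4 and 7, and 4 and 9 without tank control replicates 1 and 3. They became 0 with the compared groups alone, 2 with slide as a fixed block and 16 with scan day as a fixed block, and no scan day held enough arrays of both groups for a count of its own. At 0 min the count was 2 without handling control replicate 2, and at 30 min 6 without tank control replicate 3. Several other alternatives, array weights among them, also called probes at 30 min, and array weights called more at 60 min, with counts given below. Normexp shifted the median of all probes by up to 0.38 (at 60 min), while the main scaling shifted it by 0.11.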

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

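The tests of the spike-in level, of an ordered response to temperature and of handling shared by moved groups were chosen only after the result was seen. In 56 combinations of group and measure, 3 held an array whose gap to the nearest other was large for its group's range, where chance gives about 2.8. For the 27 probes higher in handling than in tank controls, 26.4 °C at 30 min replicate 3 was at 0.42, against 0.61 to 0.64 in its group, and 26.4 °C at 60 min replicate 1 was at 0.39, against 0.60 to 0.64. The spike-in level of 22.4 °C at 30 min replicate 1 was -1.59, against -1.12 to -1.03 in its group.

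The 2789 probes called for 22.4 °C at 60 min came from 2 arrays. Over these probes, which are not independent replicates, the change correlated at r = 0.88 (0.79 to 0.90 leaving out 1 array) with the slope on spike-in level found in the other groups (r = 0.54 over all probes, called or not), and 94.7% had the same sign, so low sample signal may account for part of the pattern. With the spike-in level as a covariate the count fell to 14, the median absolute log2 change went from 1.38 to 0.96 and the median SE from 0.37 to 0.38, so the calls ended mainly because the changes shrank. The response to 26.4 °C at 30 min cannot be told apart as a source, since the called probes moved there by a median of 0.14 in the called direction, between the bounds set for and against it. A response to 22.4 °C itself stays open and untested with 2 arrays.

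The 6 probes lower at 24.4 than at 22.4 °C were 1.83 or more apart on each of the 5 slides that held both ramps, which argues against slide. Each of these slides holds arrays that picked the set, so the size of these gaps is favoured by the choice. At 60 min, on arrays not used to pick the set, 26.4 °C lay 1.78 (SE 0.15) above 24.4 °C and 0.60 (SE 0.14) above handling controls, while 24.4 °C lay -1.18 (SE 0.15) from these, with 4 of 4 arrays apart each time, which argues against an ordered response to temperature. The exact two-sided permutation p was 0.0286, 0.00476 and 0.00476, and 0.0496 each after Benjamini-Hochberg adjustment over 26 tests. The SD among handling controls was 1.03 times that among 24.4 °C arrays, which argues against fish of mixed origin within the handling controls, and says nothing of an origin peculiar to the 24.4 °C fish. The 24.4 °C arrays lay at -1.22 ± 0.40 (SD, n = 10), beside -1.33 ± 0.06 (SD, n = 3) in tank controls, and what set them apart stays open.

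For the 27 probes higher in 60 min handling controls than in tank controls, the other arrays on the slide with most tank controls deviated from their group mates by a median of -0.12 (2 arrays, -0.31 to 0.06), which argues against slide, on few arrays. The tank control on another slide lay -1.76 from its 3 slide mates. For the 22 probes outside the set lower at 24.4 °C, every heated group lay above the tank controls, by a mean of 1.38 or more, which is consistent with an effect of handling shared by moved fish. For the other 5 this cannot be told apart: 24.4 °C at 60 min lay 0.38 (SE 0.18) above tank controls, and at 0 and 30 min, where the low level picked them, -0.13 and -0.10. The set was picked on the same 3 tank control arrays, which by itself favours a higher level in every moved group. Anything else that set these arrays apart from the moved groups stays open.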

How the results depend on the processing

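Normexp on median intensity, both scans kept, the spike-in covariate, leaving out arrays with a high spike-in level and array quality weights were chosen only after the results were seen. Of 465 alternative counts over 19 comparisons, 298 stayed within 1.5 times the count reported and 167 did not; the cause was not tested except where stated. For the 3 probes followed throughout, at 24.4 and 26.4 °C against handling controls, 426 alternative values were run. Of these, 406 kept direction and side of the threshold, 19 were no longer past it, 1 newly was, and 0 reversed. Differences between ramps are not among them. There, at 0 min, the uncalled difference between 26.4 and 24.4 °C changed sign for CUST_8949_PI428861894 (0.80, lowest -0.31) and CUST_24606_PI428861894 (-0.08, highest 0.28). At 26.4 °C, CUST_8949_PI428861894 at 30 and 60 min and CUST_34573_PI428861894 at all 3 times kept their calls under every alternative run, with adjusted p up to 0.036. Probes dim on many arrays limit what can be seen, since as few as 68.8% were well above background on an array.

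Quantile normalization and the value table each gave 6 for 26.4 against 24.4 °C at 0 min. Normexp gave 0, 5 and 9 for 22.4, 24.4 and 26.4 °C against handling controls at 0 min, 0 and 18 for 22.4 and 26.4 °C at 30 min, and 378 and 4 for 22.4 and 24.4 °C at 60 min. It gave 56 for handling against tank controls at 60 min, 0, 0 and 52 for 26.4 against 24.4 °C at 0, 30 and 60 min, and 5 and 2 for 24.4 against 22.4 °C at 30 and 60 min. Without a filter on dim probes, 26.4 against 24.4 °C at 30 min gave 1. With probes above background on every array, which tests fewer probes, 22.4 °C gave 0 at 0 and 30 min since both called probes were removed, 24.4 and 26.4 °C gave 23 and 115 at 60 min, and handling against tank controls gave 12 at 30 min.

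With the compared groups alone, which leaves fewer arrays to estimate the spread, 22.4, 24.4 and 26.4 °C gave 0, 1 and 2 at 0 min, 0, 4 and 12 at 30 min, and 1797, 2 and 8 at 60 min. The same fit gave 0 for handling against tank controls at 60 min, 0 and 0 for 26.4 against 24.4 °C at 30 and 60 min, and 5, 0 and 0 for 24.4 against 22.4 °C at 0, 30 and 60 min. Pooling the handling controls, which adds controls, gave 14, 13 and 37 for the 3 ramps at 0 min, 64 for 26.4 °C at 30 min, and 5258, 234 and 505 at 60 min.

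Slide as a random block gave 5845 and 95 for 22.4 and 24.4 °C at 60 min, 4 for handling against tank controls at 30 min, 4 for 26.4 against 24.4 °C at 30 min and 859 for 24.4 against 22.4 °C at 60 min. Slide as a fixed block gave 5 for 24.4 °C at 0 min, 0, 0 and 6 for the 3 ramps at 30 min, 7983, 2 and 410 at 60 min, and 2 for handling against tank controls at 60 min. It also gave 0, 0 and 18 for 26.4 against 24.4 °C at 0, 30 and 60 min, and 5 and 2542 for 24.4 against 22.4 °C at 30 and 60 min. Scan day as a fixed block gave 16 for handling against tank controls at 60 min, 0 for 26.4 against 24.4 °C at 0 min, and 192 for 24.4 against 22.4 °C at 60 min.

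The labels do not say that equal replicate numbers pair samples. With the replicate number as a block, 24.4 °C gave 0 at 0 min and 17 at 60 min, 26.4 °C gave 33 at 60 min, and handling against tank controls gave 4 at 60 min. The block gave 1 and 55 for 26.4 against 24.4 °C at 30 and 60 min, and 21 for 24.4 against 22.4 °C at 60 min. Under it the calls at 24.4 °C and 0 min of CUST_8949_PI428861894 (log2 3.10, adjusted p = 0.569) and CUST_34573_PI428861894 (-1.69, 0.207) were lost. In the data, 11 of 48 arrays correlated best with an array of their own number, and the number to expect by chance was not computed. Deviations from group means correlated at 0.015 on average in pairs of equal number, against -0.003 in other pairs.

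Without arrays marked as redone, 24.4 °C gave 26 at 60 min, 26.4 against 24.4 °C gave 0 at 30 min, and 24.4 against 22.4 °C gave 3 and 60 at 30 and 60 min. With both scans kept, 26.4 °C gave 70 at 30 min, handling against tank controls 12 at 30 min, and 26.4 against 24.4 °C 5 and 4 at 0 and 30 min. With the spike-in covariate, 22.4 and 24.4 °C gave 14 and 10 at 60 min, and handling against tank controls 9 and 46 at 30 and 60 min. Without arrays of high spike-in level, 26.4 °C gave 55 and 18 at 30 and 60 min, handling against tank controls 14 and 49, 26.4 against 24.4 °C 10, 5 and 43 at the 3 times, and 24.4 against 22.4 °C 45 at 60 min. Array weights gave 33 for 26.4 °C at 0 min, 48, 1989 and 829 for the 3 ramps at 30 min, 16 for 24.4 °C at 60 min, and 62 and 167 for handling against tank controls at 30 and 60 min. They gave 102, 146 and 65 for 26.4 against 24.4 °C and 19, 908 and 1302 for 24.4 against 22.4 °C at 0, 30 and 60 min.

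Leaving out 1 array gave 2 to 3 calls for 22.4 °C at 0 min, 0 to 6 for 24.4 °C and 12 to 18 for 26.4 °C, then 1 to 11 for 24.4 °C and 16 to 30 for 26.4 °C at 30 min. At 60 min it gave 244 to 3206, 17 to 167 and 19 to 611 for the 3 ramps. For handling against tank controls it gave 0 to 2, 0 to 6 and 4 to 35 at the 3 times. For 26.4 against 24.4 °C it gave 0 to 3, 0 and 22 to 543, for 24.4 against 22.4 °C 7 to 11, 2 to 6 and 31 to 1631, and for the change of the 26.4 °C response 0 to 2.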

Other observations

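Every split of the samples was planned, and the choice to compare the spike-in level between times, also by ramp, came only after the result was seen. Other splits of the same arrays into groups of the same sizes were fitted the same way, except for the comparisons with the 2 arrays of 22.4 °C at 60 min, which are too few to split. The share of splits as large, real one included, was 1 of 35 for 26.4 °C at 0 min (18 calls, highest other 2), 22.4 °C at 30 min (2 calls, highest other 1), 24.4 °C at 30 min (10 calls, highest other 1) and 26.4 °C at 30 min (29 calls, highest other 0). The share was also 1 of 35 for 26.4 against 24.4 °C at 0 min (3 calls, highest other 0) and 30 min (2 calls, highest other 0) and for 24.4 against 22.4 °C at 30 min (10 calls, highest other 3). That is the smallest share these splits can give. For handling against tank controls at 60 min, 2 of 84 splits were as large (28 calls, highest other 59). These shares are under 0.05 but were not adjusted over the 17 comparisons that were split, so none alone excludes chance. These splits take no account of slide or scan day. With slide as a fixed block limma called 16 for 26.4 °C at 0 min, 0, 0 and 6 for 22.4, 24.4 and 26.4 °C at 30 min, 0 and 0 for 26.4 against 24.4 °C at 0 and 30 min, 5 for 24.4 against 22.4 °C at 30 min, and 2 for handling against tank controls at 60 min. Scan day as a fixed block gave 0 for 26.4 against 24.4 °C at 0 min. At an unadjusted p under 0.05, with no block, 1253 and 1333 probes passed for 22.4 and 24.4 °C at 30 min, and 1273 and 974 for 26.4 against 24.4 °C at 0 and 30 min. The 2 calls for 26.4 against 24.4 °C at 30 min became 0 without any 1 of the 7 arrays, and the 28 for handling became 4 and 9 without tank control replicates 1 and 3.

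At 60 min, 3 of 100 splits for 24.4 °C and 4 of 100 for 26.4 °C were as large. Both shares are under 0.05 with no adjustment over comparisons, and only 100 of 210 possible splits were drawn, so chance is not excluded. Other splits called up to 1986 and 3371 probes against the real 45 and 68, which points to a structure of the samples. The 1986 came from the split that follows scan day, within which limma called 4 and 0 probes on days 1 and 3, with 3966 at an unadjusted p under 0.05 in the real split. For 26.4 °C, day 1 alone gave 0, with 4077 at an unadjusted p under 0.05 over all days. The share was over 0.05, so that chance stays open even with no adjustment, for 22.4 °C at 0 min (2 of 35 splits, 2 calls, highest other 3), for 26.4 against 24.4 °C at 60 min (12 of 35, 160 calls, highest other 7533) and for 24.4 against 22.4 °C at 0 min (6 of 35, 11 calls, highest other 452). The 7533 and the 452 point to a structure of the samples. The split with 7533 had a spike-in difference of -0.91, against -0.41 in the real split and 3rd of 35 in size, and that with 3371 had 0.82, against 0.35 and 2nd of 100. For 26.4 against 24.4 °C at 60 min 1 split as large follows scan day, where day 1 alone gave 31. Where limma called 0 in the real split, every split is as large whatever the data, so the splits say nothing of chance. This holds for handling against tank controls at 0 min (10 of 10; highest other 11; 1495 at an unadjusted p under 0.05) and 30 min (35 of 35; 65; 936), and for the change of the 26.4 °C response (100 of 100; 73; 1544). The 10 splits are too few for 24.4 °C at 0 min (1 of 10; 8 calls, highest other 0).

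The spike-in level of the 10 arrays taken 60 min after warming was -0.25 ± 0.67 (SD), against -1.16 ± 0.35 (SD, n = 22) at 0 and 30 min after warming (difference 0.91, two-sided permutation p = 7e-05 over arrays of any ramp). By ramp the difference was 1.34 at 22.4 °C (2 and 8 arrays; exact two-sided permutation p = 0.0222), 1.18 at 24.4 °C (4 and 6; p = 0.00476) and 0.43 at 26.4 °C (4 and 8; p = 0.255), with levels at 26.4 °C of -0.74 ± 0.60 (SD, n = 4) at 0 min and -0.54 ± 0.74 (SD, n = 4) at 60 min. With arrays permuted within ramps the mean difference was 0.98 (two-sided permutation p = 6e-05). Against the 6 handling controls at 60 min, -0.89 ± 0.42 (SD), the difference was 0.64 (exact two-sided permutation p = 0.0542).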
